A study of Arabidopsis thaliana with 21 samples.

How the data were processed

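The deposited table, whose values the authors call signal, holds 32548 genes in 21 libraries. Its values are not whole numbers, and genes without signal are listed as 0 or as a value close to 0. They look like pseudo-counts adjusted to a common library size, though no source used here says so. Per the labels, total RNA was extracted with TRIzol from plants grown for 12 days on plates and then on soil to day 30, at 22 °C with 16 h of light and 8 h of dark, and sequenced as paired 150-bp reads on a NovaSeq instrument. The tissue is labelled seedlings. The authors name bcl2fastq, HISAT2 and edgeR and the TAIR10 genome. Their versions, the counting program, its annotation and the strandedness are not given in the sources used here. No reads were analysed here.

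Gene names, transcript lengths and GC content came from the annotation and sequence of the TAIR10.1 genome. Neighbouring and overlapping genes were not checked. Genes with a mean of at least 1 over all libraries were tested, 23290 in number. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with 1 mean per genotype and a variance trend, and p-values were adjusted by the Benjamini and Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. The plan had assumed counts. The values are not, so no count model was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

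There were 13 comparisons: each mutant against Col-0, each double mutant against ada2b-c, spc against ada2a, gcn5 against ada2b-c and against ada2b-cada2a, and 2 interactions. An interaction is the change of the double mutant minus the sum of the changes of the single mutants. Gene lists were tested with camera, with a preset correlation of 0.01 and again with an estimated one, 23 lists of 343 genes in all, of which 309 were tested. Comparisons, lists, the rule for named genes and the alternative settings were fixed before the data were examined.

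The rule names GCN5, ADA2A and ADA2B in every group, up to 4 called members of a list with the largest changes and members that show why a list did not pass, and the most changed called genes whose libraries do not overlap between the groups: 5 higher and 5 lower for each mutant against Col-0, and 3 and 3 for the other comparisons. List members that moved against their list were named after the results were seen.

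The alternative settings fixed beforehand were no filter on low values, a pseudocount of 0.1, replicate number as a block, changes of at least 1 on the log2 scale, a fit of only the groups compared, each library left out in turn, and the estimated correlation. After the data were examined 7 more were added: the length and GC correction, the length slope as a covariate, equal column totals, a mean of at least 30, the library of lowest length slope in each of 4 genotypes left out (Col-0 replicate 3, gcn5 replicate 3, ada2a replicate 3 and spc replicate 2), and replicate number as a block within Col-0, gcn5 and ada2a, alone and with that correction. In these 3 genotypes the residuals of same-numbered libraries correlated at 0.16 to 0.66 for every number, so they were taken as pairs. The labels do not say so, the length slope falls from number 1 to 3 in each, and a block so chosen may understate p-values. The correction subtracts from each library a spline with 5 degrees of freedom over transcript length and GC content, fitted to 18559 genes. Also looked at were principal components, correlations of residuals, associations with length and GC content, random splits of the libraries, shuffled residuals, and 100 simulations of comparisons that share their controls.

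In a simulation of ada2b-c against Col-0, 200 of 23290 genes were changed. Without a length trend the fit found 37% of 2-fold and 88% of 4-fold changes and called 0.0303% of unchanged genes. With a length trend tied to the groups it called 44.7% of unchanged genes. After the correction it called 0.0303% and found 44% of 2-fold and 85% of 4-fold changes. Real trends may differ.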

Results

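Gene expression was measured by RNA sequencing in 21 libraries from 30-day-old Arabidopsis plants of 7 genotypes. The wild type was Col-0. The mutants were gcn5, which affects a histone acetyltransferase, ada2b-c and ada2a, which affect its adaptor proteins, spc, and the double mutants ada2b-cada2a and ada2b-cspc. Each genotype had 3 libraries. The deposited values follow an adjustment by the authors, so sequencing depth is unknown and no counting interval can be given. All Col-0 libraries listed 9029 genes near 0, those of ada2a 8441 and of spc 8170, so the adjustment may have used genotype. No label says that libraries of a genotype came from separate plants or cultures, so p-values measure only the spread between these samples. Means are ± SD over 3 libraries. Changes are log2 ± SE of the limma fit, after 1 was added to each value, which understates changes of genes with low values. The SE and p-values pool all genotypes, whose median residual SD ran from 0.101 (ada2b-c) to 0.437 (spc). The p-values are adjusted over the 23290 genes tested, and for gene lists over the 23 lists of a comparison. Camera used a preset correlation between genes. Where an estimated correlation ends the call, the adjusted p with it follows. Counts of list members that passed are over all genes tested, with that over the list alone added where it differs.

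ADA2A (AT3G07740) stood at 66.9 ± 21.3 in Col-0, at 816 ± 34.2 in ada2b-c and at 579 ± 78.7 in ada2b-cspc, which are rises of 3.64 ± 0.48 (adjusted p = 1.25e-06) and 3.14 ± 0.48 (adjusted p = 9.46e-06). In ada2b-cada2a it fell by 4.11 (adjusted p = 3.88e-07), to 3.48 ± 3.36. In gcn5 ADA2A stood at 133 ± 63.5, a difference of 0.91 that did not pass (adjusted p = 0.149) and passed without gcn5 replicate 3 (1.31, adjusted p = 0.0438), and in spc at 43.1 ± 8.59, which did not pass. In ada2a it stood at 32.0 ± 22.1, a difference of -1.18 that did not pass (adjusted p = 0.0539). That difference passed without Col-0 replicate 3 (-1.48, adjusted p = 0.0335), without ada2a replicate 3 (-1.69, adjusted p = 0.0213), with equal totals (-1.54, adjusted p = 0.0171), with genes of a mean of at least 30 (adjusted p = 0.0473), with replicate number as a block within Col-0, gcn5 and ada2a (adjusted p = 0.0485), and without 4 low-slope libraries, the one of lowest length slope in each of Col-0, gcn5, ada2a and spc (-1.99, adjusted p = 0.00261).

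GCN5 (AT3G54610) stood at 372 ± 51.0 in Col-0 and 275 ± 14.9 in gcn5, a difference of -0.43 that did not pass (adjusted p = 0.123) and passed with the length slope of each library as a covariate (-0.51, adjusted p = 0.0273) and with replicate number as a block after the transcript-length correction described below (-0.48, adjusted p = 0.034). In ada2b-c GCN5 rose by 1.0 ± 0.21 to 745 ± 83.6 (adjusted p = 0.000275). After the correction this difference was 0.32 (adjusted p = 0.17), and with the covariate 0.52 (adjusted p = 0.27). ADA2B (AT4G16420) stood at 494 ± 213 in Col-0, 583 ± 27.4 in ada2b-c, 323 ± 55.7 in ada2b-cada2a and 411 ± 62.4 in ada2b-cspc. None of these 3 differences from Col-0 passed, with adjusted p = 0.489, 0.238 and 0.684. All 3 passed with the covariate, at -2.27, -2.72 and -2.50, and that in ada2b-cada2a also after the correction (-0.89, adjusted p = 0.00855) and without the 4 low-slope libraries (-0.77, adjusted p = 0.0256). ADA2B fell by 2.03 in spc, to 127 ± 73.9 (adjusted p = 0.00068), a call that the covariate ended (-0.71, adjusted p = 0.0906). In ada2a it stood at 215 ± 51.9, a fall of 1.14 (adjusted p = 0.0277) that did not pass without Col-0 replicate 1 (-0.81, adjusted p = 0.157), ada2a replicate 2 (-1.16, adjusted p = 0.0578) or ada2a replicate 3 (-0.95, adjusted p = 0.123), in a fit of these groups alone (adjusted p = 0.0646), after the correction (-0.61, adjusted p = 0.0917) or with the covariate (-0.04, adjusted p = 0.936). The sources used here give neither the kind of mutation in each line nor the gene behind the name spc, whose transcript was not checked.

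**Figure D1:**
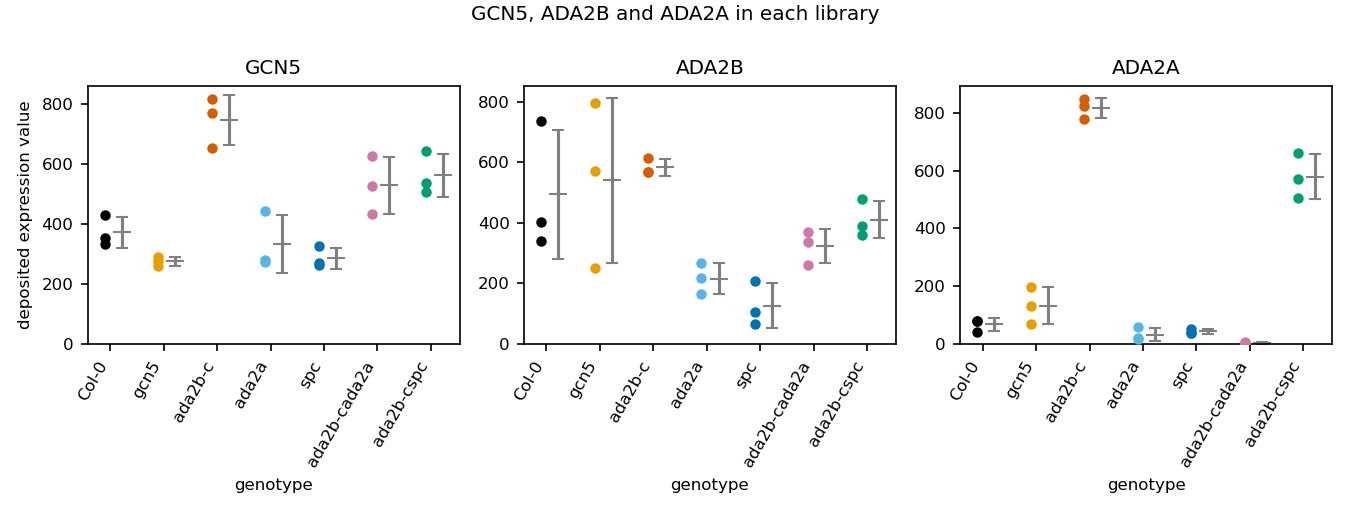
Deposited expression values of GCN5, ADA2B and ADA2A in each library, with 1 panel per gene, genotypes on the horizontal axis, 1 point per library, and the mean and SD of the 3 libraries as a grey bar beside the points. ADA2A lies at 816 ± 34.2 in ada2b-c and at 3.48 ± 3.36 in ada2b-cada2a.

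The libraries also differed in a way that followed transcript length. A line fitted to each library's deviations from the gene means had a slope per doubling of transcript length of -0.40 ± 0.21 in Col-0, -0.15 ± 0.44 in gcn5, 1.01 ± 0.05 in ada2b-c, -1.0 ± 0.25 in ada2a, -1.11 ± 0.37 in spc, 0.79 ± 0.13 in ada2b-cada2a and 0.86 ± 0.08 in ada2b-cspc. The first principal component held 71.2% of the variance and separated the 3 genotypes with the ada2b-c mutation from the others. The length trend was therefore tied to genotype, and each count below was also obtained in 2 more ways, both chosen after seeing the data. The first, below called the correction, subtracts each library's trend over transcript length and GC content before the fit. The second keeps the values and adds each library's length slope to the fit as a covariate. With equal totals, every library is scaled to the same sum.

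**Figure D2:**
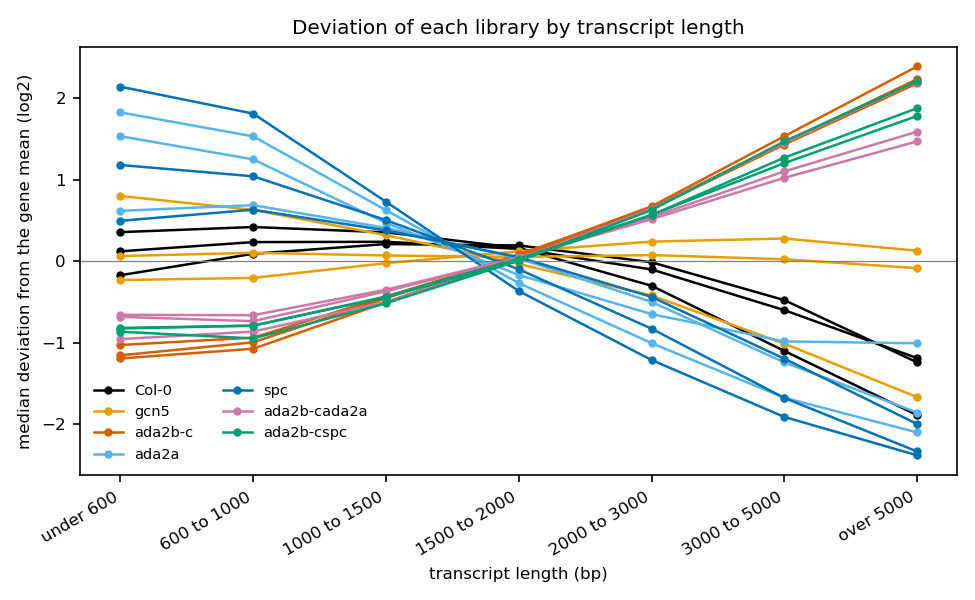
Median deviation of genes from their mean over all libraries, on the log2 scale, by class of transcript length in bp on the horizontal axis, with 1 line per library coloured by genotype. The lines of ada2b-c, ada2b-cada2a and ada2b-cspc rise with length, with mean slopes of 1.01, 0.79 and 0.86 per doubling.

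With every library scaled to the same column total, the median log2 change of all genes against Col-0 lay at 0.22 in gcn5, 0.40 in ada2b-c, -0.37 in ada2a, -0.32 in spc, 0.33 in ada2b-cada2a and 0.37 in ada2b-cspc, in place of 0, -0.06, -0.02, -0.06, -0.05 and -0.06. The balance of calls therefore depends on the scaling.

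The first comparison is gcn5 with Col-0. Of 18 genes of salicylic acid defence, 16 rose and none fell (median 2.21, adjusted p = 5.25e-15). PR1 (AT2G14610) went from 416 ± 93.3 to 14726 ± 5360, a rise of 5.11 ± 0.29 (adjusted p = 7.8e-11). PR2 (AT3G57260) rose by 4.45 ± 0.22, ALD1 (AT2G13810) by 4.28 ± 0.47 and FMO1 (AT1G19250) by 3.46 ± 0.62. UGT76B1 (AT3G11340) rose by 7.36 ± 0.58, from 6.88 ± 8.06 to 798 ± 192.

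Nuclear genes of photosynthesis fell together in gcn5. Of 24 tested, 21 fell and none rose (22 over the list alone, median -1.30, adjusted p = 1.17e-12, but p = 0.0656 with an estimated correlation). LHCB2.1 (AT2G05100) went from 226991 ± 29331 to 28459 ± 2877, a change of -2.99 ± 0.15. LHCB3 (AT5G54270) changed by -2.51 ± 0.18 and LHCB1.1 (AT1G29920) by -2.17 ± 0.20. LHCB1 and LHCB2 genes have near-identical copies, so their reads are of uncertain origin. Genes of cold and abscisic acid response fell in 13 of 15 cases, 14 over the list alone (median -1.64, adjusted p = 2.33e-08). CBF3 (AT4G25480), CBF2 (AT4G25470) and CBF1 (AT4G25490) changed by -5.26 ± 0.40, -4.52 ± 0.59 and -3.16 ± 0.38. NCED3 (AT3G14440) changed by -3.51 ± 0.25.

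Auxin genes went both ways in gcn5. Of 9 auxin response genes 5 fell and 2 rose (median -1.17, adjusted p = 0.0217, but p = 0.228 with an estimated correlation). IAA6 (AT1G52830) and IAA29 (AT4G32280) changed by -3.70 ± 0.60 and -3.66 ± 0.31, whereas GH3.3 (AT2G23170) rose by 1.87 ± 0.43. Among 14 auxin synthesis and transport genes 7 fell and 2 rose, 9 and 2 over the list alone (median -1.02, adjusted p = 0.0237, but p = 0.105 with an estimated correlation). The 2 that rose, YUC1 (AT4G32540) by 2.91 ± 0.72 and YUC4 (AT5G11320) by 2.41 ± 0.64, encode auxin synthesis enzymes. TAR2 (AT4G24670) changed by -2.25 ± 0.23. Of 12 anthocyanin and flavonoid genes 5 fell (median -0.86, adjusted p = 0.0217, but p = 0.0656 with an estimated correlation). They included the regulators PAP1 (AT1G56650) at -2.56 ± 0.53 and PAP2 (AT1G66390) at -3.17 ± 0.73, of similar sequence, and FLS1 (AT5G08640) at -1.52 ± 0.28. The jasmonate list did not pass (median -0.19, adjusted p = 0.931, and a median of 0.05 with equal totals): of 19 genes 5 rose and 6 fell (5 and 8 over the list alone), among them the defensin gene PDF1.2A (AT5G44420), which rose by 5.21 ± 0.36 to 21408 ± 9388, its regulator ORA59 (AT1G06160), which rose by 1.75 ± 0.33, and the storage protein gene VSP2 (AT5G24770), at -3.56 ± 0.29.

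In all, 7994 of 23290 genes passed in gcn5, 3630 higher and 4364 lower (4896 and 2968 with equal totals). The largest rises included AT1G74140, listed at 0 in Col-0 and at 455 ± 48.8 in gcn5, AT2G44240 at 7.31 ± 0.43, ABO3 (AT1G66600) at 6.62 ± 0.61 and AT3G44326 at 6.41 ± 0.53. AT2G15020 went from 678 ± 85.6 to 0.599 ± 1.03, a change of -8.90 ± 0.58, while EXLB1 (AT4G17030), MLP168 (AT1G35310), AT1G04660 and AT1G12010 were listed at 0 in all 3 gcn5 libraries, against 451 ± 118, 355 ± 56.6, 323 ± 19.8 and 201 ± 3.89 in Col-0. After the correction 9698 genes passed (4929 higher and 4769 lower), 7212 of them shared with the first count and none in the opposite direction. The same 7088 genes passed in the same direction in all 3 fits.

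The second comparison is ada2b-c with Col-0. Photosynthesis genes fell in 22 of 24 cases (median -2.91, adjusted p = 1.01e-12). LHCB2.1 went from 226991 ± 29331 to 1726 ± 45.5, a change of -7.03 ± 0.15, and LHCB3 changed by -6.02 ± 0.18. Of the 18 salicylic acid defence genes 16 rose and 1 fell (median 2.64, adjusted p = 2.05e-06). FMO1 rose by 4.04 ± 0.62, ALD1 by 3.94 ± 0.47, and WRKY38 (AT5G22570) and SARD1 (AT1G73805) by 3.84 ± 0.24 and 3.80 ± 0.18. The exception was PR5 (AT1G75040) at -1.0 ± 0.15, which lost its call after the correction (-0.28) and with equal totals (-0.46). FMO1 lost its call with the covariate (1.83).

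Cold and abscisic acid genes fell in 13 of 15 cases in ada2b-c and 1 rose (median -3.37, adjusted p = 2.67e-05). CBF2, CBF3 and CBF1 changed by -7.64 ± 0.59, -7.00 ± 0.40 and -5.95 ± 0.38. HAI1 (AT5G59220) rose by 0.75 ± 0.28, which did not pass without Col-0 replicate 1 (adjusted p = 0.0821), Col-0 replicate 3 (0.0698) or ada2b-c replicate 2 (0.0529), or after the correction (0.175). Of 12 anthocyanin and flavonoid genes 11 fell, 6 with the covariate (median -3.10, adjusted p = 0.000495), with PAP1 at -4.79 ± 0.53 and LDOX (AT4G22880) at -4.42 ± 0.40.

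Flower genes were lower in ada2b-c. Of 13 floral organ identity genes 11 fell (median -3.99, adjusted p = 0.000495). The transcription factor genes SEP1 (AT5G15800) and AP3 (AT3G54340) changed by -5.75 ± 0.40 and -4.72 ± 0.50. AG (AT4G18960) was listed at 0 in all 3 ada2b-c libraries, against 131 ± 10.2 in Col-0. Of 14 markers of the anther tapetum 10 fell and 2 rose (median -3.13, adjusted p = 0.02, but p = 0.179 with an estimated correlation). The pollen-coat genes GRP17 (AT5G07530), EXL4 (AT1G75910) and EXL6 (AT1G75930) were listed at 0, against 276 ± 85.3, 216 ± 53.9 and 122 ± 30.3 in Col-0. The 2 that rose, LAP6 (AT1G02050) by 3.17 ± 0.37 and TKPR1 (AT4G35420) by 2.04 ± 0.26, encode enzymes of pollen wall synthesis.

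Hormone genes of auxin and cytokinin were also tested in ada2b-c. Of 14 auxin synthesis and transport genes 12 fell and 1 rose (median -2.30, adjusted p = 0.000752). YUC8 (AT4G28720) and YUC9 (AT1G04180) changed by -5.14 ± 0.42 and -4.71 ± 0.43, whereas YUC4 rose by 2.67 ± 0.64. All 9 auxin response genes changed, 7 down and 2 up (median -3.98, -2.37 after the correction and -2.33 with the covariate, adjusted p = 0.0102, but p = 0.151 with an estimated correlation). IAA6 and IAA29 changed by -7.23 ± 0.60 and -7.16 ± 0.31, and the 2 that rose, GH3.3 by 4.87 ± 0.43 and GH3.5 (AT4G27260) by 3.60 ± 0.28, encode enzymes that conjugate auxin. Of 21 cytokinin genes 14 fell and 2 rose, 15 and 2 over the list alone (median -1.72, adjusted p = 0.00296, but p = 0.121 with an estimated correlation). With the covariate 4 fell and 1 rose (median -0.72). CKX4 (AT4G29740) changed by -5.32 ± 0.30 and the response regulator gene ARR15 (AT1G74890) by -3.61 ± 0.33. The 2 that rose were CKX1 (AT2G41510) by 2.83 ± 0.56, a call that the covariate ended (0.56), and LOG5 (AT4G35190) by 2.41 ± 0.49.

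Of 19 subunit genes of the GCN5 complexes 12 rose and 2 fell in ada2b-c (median 1.27, 0.56 with the covariate, adjusted p = 0.00409, but p = 0.121 with an estimated correlation). The 3 largest rises were in long transcripts. TRA1A (AT2G17930, 12118 bp) rose by 5.47 ± 0.44, TRA1B (AT4G36080, 12133 bp) by 5.21 ± 0.50 and SPT20 (AT1G72390, 4707 bp) by 5.11 ± 0.56. After the correction TRA1A stood at 0.10 and TRA1B at -0.18, without passing, and SPT20 at 2.19 (adjusted p = 5.99e-06). The 2 that fell, TAF10 (AT4G31720) by 0.53 ± 0.18 and ENY2 (AT3G27100) by 0.74 ± 0.31, stood at 0.76 and 0.55 after that correction and at 0.56 and 1.29 with the covariate. With equal totals they stood at 0.02 and -0.20 and did not pass. ENY2 also failed without Col-0 replicate 2 (adjusted p = 0.0557), Col-0 replicate 3 (0.14) or ada2b-c replicate 1, 2 or 3 (0.0902, 0.0572 and 0.0889), and TAF10 without Col-0 replicate 3 (0.0678) or ada2b-c replicate 2 (0.0522).

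In all, 15372 genes passed in ada2b-c, 7535 higher and 7837 lower (9578 and 5538 with equal totals). DIN2 (AT3G60140) was listed at 0 in Col-0 and stood at 989 ± 48.2, and ABCG37 (AT3G53480) and AT1G74140 were listed at 0 in Col-0 and stood at 288 ± 25.8 and 250 ± 33.7. UGT76B1 rose by 9.15 ± 0.58 and AT5G09290 by 7.73 ± 0.50. AT1G66100 went from 12349 ± 2411 to 10.8 ± 8.36, a change of -10.40 ± 0.48. AT5G37940 changed by -9.41 ± 0.56, BBX16 (AT1G73870) by -9.37 ± 0.51, AT2G34655 by -9.15 ± 0.38, and GolS3 (AT1G09350) by -8.82 ± 0.54. Across genes, which are not independent replicates, the changes followed transcript length with a rank correlation of 0.56, and the median length was 2266 bp for genes called higher and 1330 bp for genes called lower. After the correction 14978 genes passed (8310 higher and 6668 lower), of which 10560 were called in the same direction before and 863 in the opposite one, and with the covariate 10003 passed. The same 5299 genes passed in the same direction in all 3 fits.

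The comparison of ada2a with Col-0 follows. None of the 23 lists passed, with the lowest adjusted p = 0.0977 for flowering-time regulators, of which 9 of 19 rose and 1 fell (11 and 1 over the list alone, 3 and 1 both with the covariate and with equal totals, median 0.52). TSF (AT4G20370) rose by 2.94 ± 0.57, FUL (AT5G60910) by 1.36 ± 0.28, and MAF5 (AT5G65080), a repressor of flowering, changed by -1.46 ± 0.31. MAF5 did not pass in a fit of ada2a and Col-0 alone (adjusted p = 0.058). The flowering-time list and the cytokinin list, in which 8 of 21 genes rose and 1 fell (5 and 2 after the correction, 2 and 0 with the covariate, median 0.88, adjusted p = 0.103), both passed without Col-0 replicate 3, at adjusted p = 0.042. Of 19 jasmonate genes 9 rose and 2 fell (10 and 2 over the list alone, 4 and 4 with equal totals, median 0.53, adjusted p = 0.138), with JAZ8 (AT1G30135) at 3.18 ± 0.56 and AOC1 (AT3G25760) at -1.13 ± 0.19. The salicylic acid list did not pass (3 higher and 4 lower of 18, 5 and 1 with the covariate and 2 and 7 with equal totals, median -0.08, adjusted p = 0.87), although PR1 rose by 1.98 ± 0.29, while ICS1 (AT1G74710) changed by -0.97 ± 0.20.

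In all, 9235 genes passed in ada2a, 4606 higher and 4629 lower (2642 and 7146 with equal totals). The largest rises included AT5G44306 at 6.44 ± 0.66, AT5G53740 at 5.28 ± 0.66 and AT5G37478 at 5.15 ± 0.80. AT4G00975 rose by 5.32 ± 0.60. It is annotated as an antisense RNA, and because the strandedness of the libraries is not given its reads are of uncertain origin. The small nucleolar RNA AT1G03746 was listed at 0 in Col-0 and stood at 42.9 ± 21.8. The noncoding RNA AT2G01422 changed by -4.04 ± 0.61 and AT4G16680 by -3.83 ± 0.59, while AT3G56790, AT3G47110 and AT4G11400 were listed at 0 in ada2a, against 15.6 ± 5.20, 15.0 ± 7.66 and 12.2 ± 3.98 in Col-0. Changes followed transcript length with a rank correlation of -0.52 across genes. The count was 7725 after the correction (5454 genes shared, 44 opposite), 3745 with the covariate (2292 higher and 1453 lower) and 2099 in the same direction in all 3 fits, and it was 4804 in a fit of these groups alone (2824 higher and 1980 lower), 5382 with changes of at least 1, 5528 without Col-0 replicate 1 and 4600 without ada2a replicate 3.

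The comparison of spc with Col-0 is next. Jasmonate genes were higher: 11 of 19 rose and 1 fell (median 1.21, 0.78 after the correction, adjusted p = 1.15e-05, but p = 0.0662 with an estimated correlation). JAZ8 rose by 4.60 ± 0.56, to 1432 ± 1034, JAZ10 (AT5G13220) by 3.24 ± 0.21 and the thionin gene THI2.1 (AT1G72260) by 2.85 ± 0.34. PDF1.2A rose by 1.54 ± 0.36, but not in a fit of these groups alone (adjusted p = 0.0504), after the correction (-0.05) or with the covariate (0.30). Reads of PDF1.2A and its near-identical copies cannot be told apart with certainty. The gene that fell, LOX2 (AT3G45140), changed by -0.76 ± 0.29. It stood at 0.06 after that correction and -0.05 with the covariate, and did not pass without Col-0 replicate 1 (adjusted p = 0.12), Col-0 replicate 2 (0.114), or spc replicate 1, 2 or 3 (0.0514, 0.077 and 0.0849).

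Of 21 cytokinin genes in spc 7 rose and 1 fell, 4 and 1 with the covariate (medians 0.93 and 0.38, adjusted p = 0.0162, but p = 0.533 with an estimated correlation). The response regulator genes ARR5 (AT3G48100) and ARR6 (AT5G62920) rose by 2.27 ± 0.34 and 1.95 ± 0.26, and IPT3 (AT3G63110) changed by -1.50 ± 0.27. Of 13 floral organ identity genes 5 rose, 2 with the covariate (median 1.03, adjusted p = 0.0162, but p = 0.193 with an estimated correlation). SEP3 (AT1G24260) and PI (AT5G20240) rose by 1.54 ± 0.33 and 1.53 ± 0.29. The floral list lost its call without spc replicate 1 (adjusted p = 0.0614) and after the correction (adjusted p = 0.0986).

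Photosynthesis genes were lower in spc, with 10 of 24 down and none up (median -0.32, adjusted p = 0.0162, but p = 0.603 with an estimated correlation, and 0.0614 without spc replicate 1). After the correction 17 were down (median -0.52, adjusted p = 3.02e-05, but p = 0.209 with an estimated correlation) and with equal totals 18 (median -0.59, adjusted p = 0.000419, but p = 0.487 with that), and with the covariate 5. RBCS2B (AT5G38420) changed by -1.22 ± 0.26, and RCA (AT2G39730) by -1.43 ± 0.34, without passing in a fit of these groups alone (adjusted p = 0.0622) or with the covariate (-0.30). Of 18 salicylic acid defence genes 7 rose and 1 fell (median 0.21, adjusted p = 0.0328, but p = 0.589 with an estimated correlation), which became -0.06 with equal totals (adjusted p = 0.108). After the correction 12 rose and 1 fell (median 0.61, adjusted p = 3.27e-05, and p = 0.0471 with an estimated correlation), and the median was 0.73 with the covariate. This list also lost its call without Col-0 replicate 3 (adjusted p = 0.135) and without spc replicate 1 (0.131). PR1 rose by 3.14 ± 0.29 to 3892 ± 1949, WRKY18 (AT4G31800) by 1.79 ± 0.20 and PR2 by 1.38 ± 0.22. WRKY70 (AT3G56400) was the gene that fell, at -0.84 ± 0.21, a call lost in a fit of these groups alone (adjusted p = 0.0675) and with the covariate (-0.30).

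In all, 11025 genes passed in spc, 5047 higher and 5978 lower (3523 and 7389 with equal totals). AT4G29370 was listed at 0 in Col-0 and stood at 72.1 ± 5.61, and AT3G53600, AT2G41470, AT3G06095 and AT4G35655 rose by 5.75 ± 0.76, 5.30 ± 0.73, 5.23 ± 0.80 and 5.09 ± 0.57. AT2G15020 changed by -5.35 ± 0.58, AT3G45430 by -5.28 ± 0.81, AT2G40960 by -5.13 ± 0.54, HCS2 (AT1G37150) by -5.03 ± 0.79 and AT5G42760 by -4.53 ± 0.55. Changes followed transcript length with a rank correlation of -0.57 across genes, with a median length of 1111 bp for genes called higher and 2120 bp for genes called lower. The count was 8665 after the correction (6284 genes shared, 50 opposite), 3146 with the covariate (1728 higher and 1418 lower) and 1941 in the same direction in all 3 fits, and it was 4443 in a fit of these groups alone (2339 and 2104), 6947 with changes of at least 1, 7340 without Col-0 replicate 1 and 6730 without spc replicate 2.

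Next is the double mutant ada2b-cada2a against Col-0. Photosynthesis genes fell in 22 of 24 cases (median -2.16, adjusted p = 6.63e-12, but p = 0.0694 with an estimated correlation). LHCB2.1 changed by -6.54 ± 0.15 and LHCB3 by -4.67 ± 0.18. Salicylic acid defence genes rose in 15 of 18 cases, 16 over the list alone (median 2.85, adjusted p = 1.52e-08). PR2 rose by 4.39 ± 0.22 to 20237 ± 1307, EDS5 (AT4G39030) by 3.83 ± 0.23 and ALD1 by 3.66 ± 0.47. Cold and abscisic acid genes fell in 13 of 15 cases (median -3.11, adjusted p = 1.33e-06), with CBF2 at -8.90 ± 0.59.

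Of 13 floral organ identity genes in ada2b-cada2a 10 fell, 6 with the covariate (median -1.94, -1.17 after the correction, adjusted p = 0.0108, but p = 0.0694 with an estimated correlation and 0.0925 after the correction). AG and SEP3 changed by -3.47 ± 0.40 and -3.28 ± 0.33. Of 12 anthocyanin and flavonoid genes 9 fell, 4 with the covariate (median -1.95, adjusted p = 0.0212, but p = 0.0694 with an estimated correlation), with FLS1 at -2.96 ± 0.28. Of 19 jasmonate genes 11 fell and 3 rose, 13 and 3 over the list alone (median -0.93, -0.48 after the correction and -0.50 with equal totals, adjusted p = 0.0263, but p = 0.225 with an estimated correlation and 0.156 after the correction). The synthesis genes AOC1 and AOS (AT5G42650) changed by -3.82 ± 0.19 and -3.43 ± 0.19, while PDF1.2A rose by 1.12 ± 0.36.

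Of 21 cytokinin genes in ada2b-cada2a 12 fell and 2 rose, 5 and 1 with the covariate (median -1.11, -0.43 after the correction, -0.35 with the covariate and -0.68 with equal totals, adjusted p = 0.0263, but p = 0.265 with an estimated correlation and 0.161 after the correction). ARR15 and CKX4 changed by -2.88 ± 0.33 and -2.71 ± 0.30 and LOG5 rose by 2.86 ± 0.49. Of 14 auxin synthesis and transport genes 11 fell and 3 rose, 7 and 1 with the covariate (median -1.35, adjusted p = 0.0455, but p = 0.157 with an estimated correlation). Those that rose were YUC4 by 2.75 ± 0.64, YUC1 by 2.5 ± 0.72 and YUC3 (AT1G04610) by 2.45 ± 0.58, the last 2 without passing with the covariate (1.49 and 1.42). This list lost its call without Col-0 replicate 1 (adjusted p = 0.0556), Col-0 replicate 2 (0.0573), ada2b-cada2a replicate 1 (0.0511) or ada2b-cada2a replicate 3 (0.0516), and with equal totals (0.0609).

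GCN5 stood at 528 ± 95.4 in ada2b-cada2a, 0.50 ± 0.21 above Col-0 (adjusted p = 0.0436), a call lost without Col-0 replicate 2 (adjusted p = 0.136), Col-0 replicate 3 (0.104), ada2b-cada2a replicate 1 (0.182) or 3 (0.0897) or the 4 low-slope libraries (0.0716), at 0.09 with the covariate and -0.12 after the correction. In all, 14570 genes passed, 7085 higher and 7485 lower (8769 and 5266 with equal totals). DIN2, AT1G74140 and AT5G16900 were listed at 0 in Col-0 and stood at 344 ± 102, 650 ± 122 and 300 ± 13.5, and RLP7 (AT1G47890) and AT2G44240 rose by 8.42 ± 0.67 and 8.00 ± 0.43. CIPK20 (AT5G45820) changed by -9.63 ± 0.53, AT3G55240 by -9.37 ± 0.51, AT5G37940 by -9.37 ± 0.56 and BBX16 by -9.07 ± 0.51, and AT2G15020 was listed at 0. The correction left 13614 calls (7357 higher and 6257 lower, 9780 shared, 570 opposite), with the covariate 9632, and 5214 in the same direction in all 3 fits.

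Then ada2b-cspc was compared with Col-0. Photosynthesis genes fell in 22 of 24 cases, 23 over the list alone (median -2.52, adjusted p = 4.01e-12, but p = 0.0592 with an estimated correlation). LHCB2.1 changed by -6.56 ± 0.15 and LHCB3 by -4.96 ± 0.18. Salicylic acid defence genes rose in 17 of 18 cases (median 2.98, adjusted p = 3.05e-08). PR2 rose by 3.97 ± 0.22, ALD1 by 3.63 ± 0.47 and EDS5 by 3.56 ± 0.23. Of 15 cold and abscisic acid genes 13 fell and 2 rose (median -3.07, adjusted p = 1.75e-05). CBF2 and KIN1 (AT5G15960) changed by -7.47 ± 0.59 and -6.39 ± 0.62.

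Of 13 floral organ identity genes in ada2b-cspc 9 fell (median -2.23, -1.13 after the correction, adjusted p = 0.00593, but p = 0.0592 with an estimated correlation), with AG at -5.92 ± 0.40. Of 14 tapetum markers 10 fell and 2 rose (median -3.27, adjusted p = 0.0247, but p = 0.206 with an estimated correlation). GRP17 and EXL6 changed by -7.78 ± 0.54 and -6.44 ± 0.45, and the pollen wall genes TKPR1 and LAP6 rose by 2.04 ± 0.26 and 2.67 ± 0.37, the latter without passing with the covariate (1.18). Of 19 jasmonate genes 11 fell and 2 rose (median -1.0, -0.33 after the correction and -0.51 with equal totals, adjusted p = 0.0247, but p = 0.206 with an estimated correlation and 0.107 after the correction), with AOC1 at -4.44 ± 0.19 and AOS at -3.79 ± 0.19. Of 12 anthocyanin and flavonoid genes 8 fell, 5 with the covariate (median -1.88, adjusted p = 0.0247, but p = 0.0592 with an estimated correlation), with FLS1 at -3.78 ± 0.28.

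Of 14 auxin synthesis and transport genes in ada2b-cspc 11 fell and 2 rose, 7 and 1 with the covariate and 7 and 3 with equal totals (median -1.47, adjusted p = 0.0353, but p = 0.144 with an estimated correlation). YUC8 and TAR2 changed by -2.60 ± 0.42 and -2.52 ± 0.23, while YUC4 rose by 2.89 ± 0.64. Of 21 cytokinin genes 13 fell and 3 rose, 14 and 3 over the list alone, 8 and 4 after the correction and 4 and 1 with the covariate (median -1.22, -0.70 after the correction, -0.06 with the covariate and -0.74 with equal totals, adjusted p = 0.0493, but p = 0.296 with an estimated correlation and 0.249 after the correction). CKX4 changed by -2.78 ± 0.30 and LOG5 rose by 3.36 ± 0.49. The cytokinin list lost its call without Col-0 replicate 2 (adjusted p = 0.0505), Col-0 replicate 3 (0.0737) or ada2b-cspc replicate 1 (0.0712). Of 19 subunit genes of the GCN5 complexes 11 rose and 4 fell (median 1.08, 0.57 after the correction and 0.38 with the covariate, adjusted p = 0.0283, but p = 0.211 with an estimated correlation). TRA1A rose by 4.93 ± 0.44, TRA1B by 4.73 ± 0.50 and SPT20 by 4.69 ± 0.56. After the correction the first 2 stood at 0.04 and -0.17, without passing, and SPT20 at 1.93 (adjusted p = 3.26e-05).

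GCN5 stood at 562 ± 72.1 in ada2b-cspc, 0.60 ± 0.21 above Col-0 (adjusted p = 0.0171), a call lost without Col-0 replicate 2 (adjusted p = 0.0667) or ada2b-cspc replicate 3 (0.0789), at 0.16 with the covariate and -0.05 after the correction. In all, 15051 genes passed, 7307 higher and 7744 lower (9136 and 5329 with equal totals). DIN2, AT1G74140 and GAT1_2.1 (AT1G15040) were listed at 0 in Col-0 and stood at 2100 ± 127, 918 ± 88.3 and 358 ± 13.5, and UGT76B1 and RLP7 rose by 8.56 ± 0.58 and 8.51 ± 0.67. CYP96A15 (AT1G57750) changed by -10.38 ± 0.41, BBX16 by -10.05 ± 0.51, LTP4 (AT5G59310) by -9.77 ± 0.52 and AT3G55240 by -9.71 ± 0.51, and AT2G15020 was listed at 0. The correction left 14210 calls (7626 higher and 6584 lower, 10234 shared, 667 opposite), with the covariate 9959, and 5395 in the same direction in all 3 fits.

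**Figure D3:**
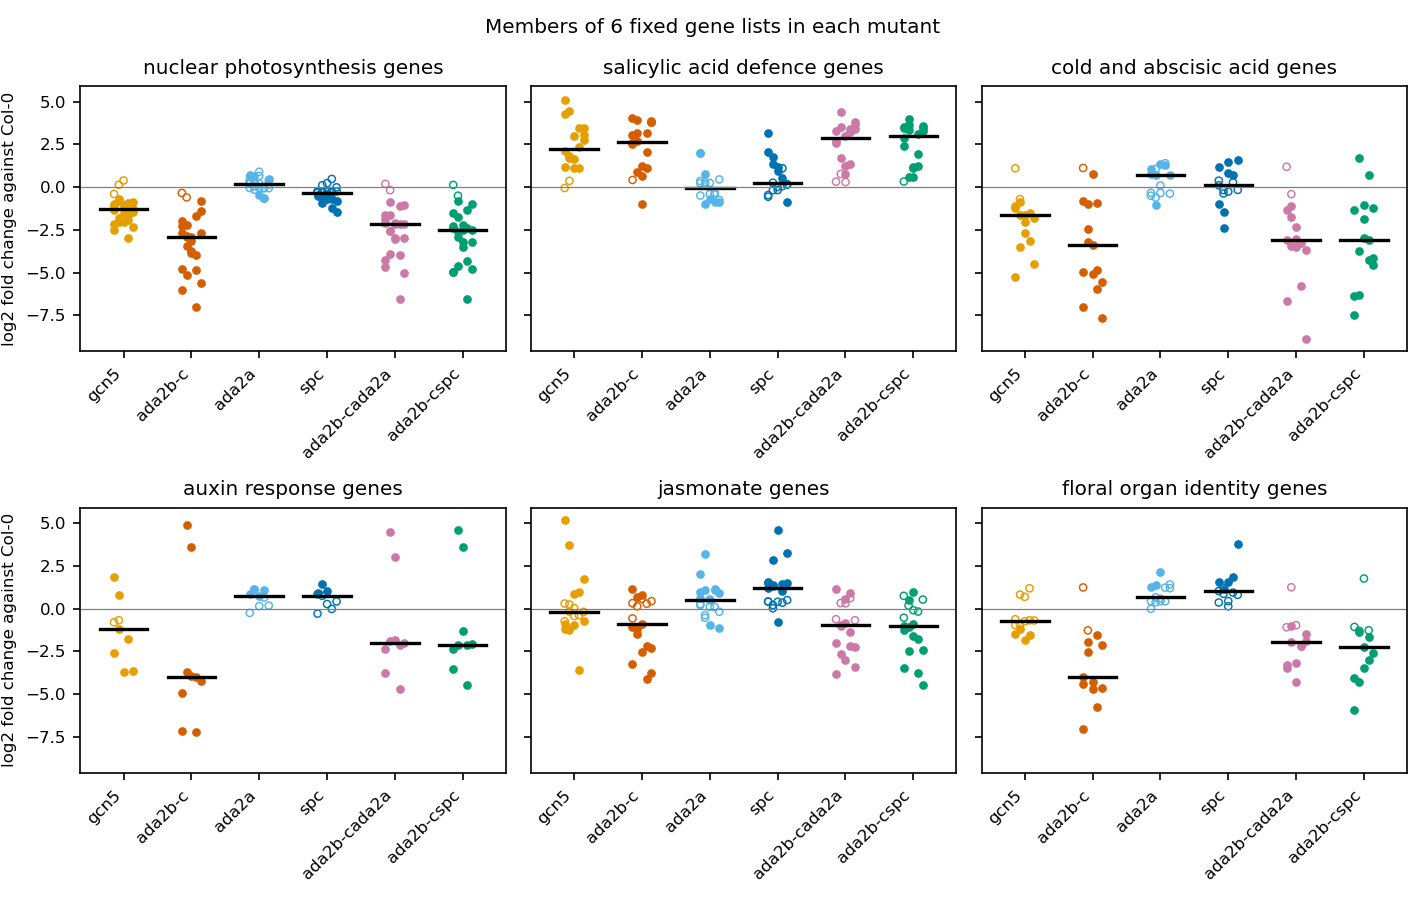
Log2 change against Col-0 of each tested member of 6 gene lists (vertical axis) in each mutant (horizontal axis), with 1 point per gene, filled where it passed at an adjusted p under 0.05, and a black bar at the list median. Photosynthesis genes have medians of -1.30 in gcn5 and -2.91 in ada2b-c.

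Here ada2b-cada2a was compared with ada2b-c. ADA2A changed by -7.76 ± 0.48. Photosynthesis genes were higher in the double mutant in 14 of 24 cases, 17 over the list alone (median 0.61, adjusted p = 3.16e-09, but p = 0.0666 with an estimated correlation). LHCB3 went from 6618 ± 126 to 17053 ± 3219, a rise of 1.35 ± 0.18. Of 9 auxin response genes 7 rose (median 2.14, adjusted p = 2.77e-06), IAA29 by 3.41 ± 0.31 and IAA1 (AT4G14560) by 2.58 ± 0.23. Of 14 auxin synthesis and transport genes 8 rose, 4 with equal totals (median 0.83, adjusted p = 9.42e-06), YUC3 by 5.05 ± 0.58 and YUC8 by 3.13 ± 0.42. Of 12 anthocyanin and flavonoid genes 8 rose, 5 with equal totals (median 1.3, adjusted p = 6.42e-05), LDOX by 2.32 ± 0.40 and TT19 (AT5G17220) by 1.94 ± 0.46.

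Of 13 floral organ identity genes 6 were higher in ada2b-cada2a than in ada2b-c (median 0.72, adjusted p = 0.000228), SEP1 by 3.54 ± 0.40. AG, listed at 0 in ada2b-c, stood at 11.1 ± 2.75. Of 14 tapetum markers 6 were higher, 7 over the list alone (median 1.90, adjusted p = 4.9e-05). EXL4 and GRP17, listed at 0 in ada2b-c, stood at 29.5 ± 6.31 and 28.2 ± 10.2. Of 21 cytokinin genes 4 rose (median 0.59, adjusted p = 0.0106, but p = 0.188 with an estimated correlation), led by CKX4 at 2.61 ± 0.30. Of 13 mitotic cell cycle genes 3 rose, 6 over the list alone, 5 after the correction, 9 with the covariate and 1 with equal totals (median 0.67, adjusted p = 0.00147, but p = 0.0501 with an estimated correlation). Of 3 seed and embryo markers 2 were higher (median 2.35, adjusted p = 0.0202, but p = 0.0666 with an estimated correlation), and both, FUS3 (AT3G26790) and EM6 (AT2G40170), were listed at 0 in ada2b-c. The list of GCN5 complex subunits lay lower (median -0.51, adjusted p = 0.000321, but p = 0.0533 with an estimated correlation), and ADA2A was the only one of its 19 genes to pass.

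In all, 3646 genes differed between ada2b-cada2a and ada2b-c, 2202 higher and 1444 lower (1670 and 1548 with equal totals). AT1G10300 and AT1G10980 rose by 6.13 ± 0.91 and 6.09 ± 0.38. ATA27 (AT1G75940) was listed at 0 in ada2b-c and stood at 52.9 ± 12.5. AT3G01345 went from 1757 ± 107 to 7.04 ± 0.618, a change of -7.77 ± 0.55, and HCS2 changed by -6.68 ± 0.79. The count was 5494 after the correction (2861 higher and 2633 lower), 6965 with the covariate, 6583 without the 4 low-slope libraries, 8861 in a fit of these groups alone (4595 and 4266) and 2169 with changes of at least 1. It was 2265, 2427 and 2409 without ada2b-c replicate 1, 2 and 3, and 2401 without ada2b-cada2a replicate 2.

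The comparison of ada2b-cspc with ada2b-c uses the same ada2b-c libraries. Of 9 auxin response genes 7 rose (median 2.16, adjusted p = 3.14e-09), IAA29 by 3.64 ± 0.31 and IAA1 by 2.59 ± 0.23. Among 14 auxin synthesis and transport genes 6 rose, 10 over the list alone (median 0.93, adjusted p = 1.61e-06), YUC3 by 3.76 ± 0.58. Photosynthesis genes were higher in 4 of 24 cases, 9 over the list alone and 11 with the covariate (median 0.47, adjusted p = 4.33e-06, but p = 0.148 with an estimated correlation), LHCB3 by 1.05 ± 0.18. Among 12 anthocyanin and flavonoid genes 6 rose, 8 over the list alone (median 1.25, adjusted p = 3.74e-05), TT19 by 2.23 ± 0.46 and LDOX by 2.12 ± 0.40. Among 21 cytokinin genes 4 rose, 9 over the list alone, 7 after the correction and 8 with the covariate (median 0.58, adjusted p = 0.000201, but p = 0.0597 with an estimated correlation), CKX4 by 2.54 ± 0.30. Among 13 floral organ identity genes 4 rose, 6 over the list alone (median 0.88, adjusted p = 0.0013), SEP1 by 2.77 ± 0.40.

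Leaf senescence genes were higher in ada2b-cspc than in ada2b-c in 3 of 16 cases, 4 over the list alone and 5 with the covariate (median 0.25, adjusted p = 0.0205, but p = 0.0682 with an estimated correlation). They were SAG12 (AT5G45890), which rose by 6.81 ± 0.56 to 377 ± 83.2, SAG29 (AT5G13170) by 3.21 ± 0.41 and RNS1 (AT2G02990) by 2.94 ± 0.46. Of 16 gibberellin genes 3 rose, 5 over the list alone and with the covariate (median 0.48, adjusted p = 0.0374, but p = 0.0682 with an estimated correlation and 0.12 without ada2b-c replicate 2). GA20OX1 (AT4G25420) rose by 4.15 ± 0.60 and GA2OX8 (AT4G21200) by 2.94 ± 0.62. Of 12 strigolactone and branching genes 2 rose (median 0.37, adjusted p = 0.0374, but p = 0.299 with an estimated correlation and 0.0718 with equal totals), the larger being MAX4 (AT4G32810) by 2.04 ± 0.32. That list lost its call without ada2b-c replicate 2 (adjusted p = 0.0511), ada2b-c replicate 3 (0.0529) or ada2b-cspc replicate 3 (0.0598).

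Further lists lay apart between ada2b-cspc and ada2b-c with few genes past the threshold. Of 13 mitotic genes none passed over all genes and 3 over the list alone (median 0.49, adjusted p = 0.0013, but p = 0.0522 with an estimated correlation). Of 3 seed and embryo markers FUS3, listed at 0 in ada2b-c, stood at 14 ± 3, and 2 passed over the list alone (median 2.1, adjusted p = 0.014, but p = 0.0597 with an estimated correlation). None of 19 GCN5 complex subunits passed (median -0.35, adjusted p = 0.0183, but p = 0.154 with an estimated correlation). Of 11 meristem genes 1 passed (median 0.49, adjusted p = 0.0374, but p = 0.135 with an estimated correlation), and that list lost its call without ada2b-c replicate 3 (adjusted p = 0.15), ada2b-cspc replicate 1 (0.0661) or ada2b-cspc replicate 3 (0.0569).

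In all, 2137 genes differed between ada2b-cspc and ada2b-c, 1370 higher and 767 lower. The noncoding RNA AT2G01422 went from 8.78 ± 3.23 to 5625 ± 735, a rise of 9.21 ± 0.61, and PGAZAT (AT2G41850) from 2.04 ± 1.11 to 358 ± 12.2, a rise of 6.94 ± 0.88. AT3G01345 changed by -8.69 ± 0.55 and AT2G40960 by -7.23 ± 0.54, and HCS2 was listed at 0 in ada2b-cspc. The count was 3600 after the correction (1871 higher and 1729 lower), 4998 with the covariate, 4166 without the 4 low-slope libraries, 7363 in a fit of these groups alone (3651 and 3712) and 1423 with changes of at least 1. It was 1348, 1364 and 1390 without ada2b-c replicate 1, 2 and 3, and 1234 and 1280 without ada2b-cspc replicate 1 and 2.

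The mutants spc and ada2a were also compared. Jasmonate genes were higher in spc in 5 of 19 cases, 9 over the list alone (median 0.59, adjusted p = 1.53e-12). JAZ10 stood at 3119 ± 945 in spc and 677 ± 74.1 in ada2a, a difference of 2.16 ± 0.21, and AOC1 differed by 1.48 ± 0.19. Of 18 salicylic acid defence genes 3 were higher, 5 over the list alone, 7 after the correction and 8 with the covariate (median 0.41, adjusted p = 7.88e-08). These were WRKY18 at 1.54 ± 0.20, PR2 at 1.15 ± 0.22 and PR5 at 0.79 ± 0.15, and PR2 lost its call without ada2a replicate 2 (adjusted p = 0.0589) or replicate 3 (0.0512). Photosynthesis genes were lower in spc, with 3 of 24 passing, 14 over the list alone and with the covariate and 1 with equal totals (median -0.54, adjusted p = 6.25e-14, but p = 0.061 with an estimated correlation). The largest difference was in RBCS2B at -1.26 ± 0.26, which lost its call without ada2a replicate 2 (-0.92) or spc replicate 3 (-1.07).

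In all, 241 genes differed between spc and ada2a, 153 higher and 88 lower (131 and 38 with equal totals), in the fit of all 21 libraries. In a limma fit of these 6 libraries alone none passed, none of the genes named for this comparison included, and 1455 had an unadjusted p under 0.05. AT2G30830 was higher in spc by 4.16 ± 0.62, and GH9B6 (AT1G23210) and AT3G11990, listed at 0 in ada2a, stood at 13.1 ± 3.12 and 13.3 ± 8.10 in spc. AT4G00975 was lower by 3.87 ± 0.60 and UGT71C2 (AT2G29740) by 3.68 ± 0.68, and AT5G06795, listed at 0 in spc, stood at 13.7 ± 7.24 in ada2a. Without ada2a replicate 2 GH9B6 (adjusted p = 0.0763), AT5G06795 (0.0712) and UGT71C2 (0.0727) did not pass, nor did GH9B6 (0.0501) and UGT71C2 (0.0604) without spc replicate 3. GH9B6 (0.0584) and AT4G00975 (0.0648) failed with a pseudocount of 0.1, and GH9B6 with equal totals (0.0517). The count was 564 without ada2a replicate 1, 82 without ada2a replicate 2, 505 without spc replicate 1 (195 higher and 310 lower), 115 without spc replicate 3, 642 after the correction, 1611 with the covariate (762 and 849) and 598 without the 4 low-slope libraries (244 and 354).

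Then gcn5 was compared with ada2b-c. Photosynthesis genes were higher in gcn5 in 22 of 24 cases (median 1.72, adjusted p = 3.38e-11, but p = 0.0867 with an estimated correlation), LHCB2.1 by 4.04 ± 0.15. Among 13 floral organ identity genes 10 were higher (median 2.46, adjusted p = 0.000527), SEP1 by 4.57 ± 0.40. Of 14 tapetum markers 10 were higher and 2 lower (median 3.38, adjusted p = 0.002, but p = 0.116 with an estimated correlation). EXL4, listed at 0 in ada2b-c, stood at 579 ± 81.2 in gcn5, and the 2 that were lower were TKPR1 at -1.75 ± 0.26 and LAP6 at -1.93 ± 0.37, the latter without passing with the covariate (-0.56). Of 14 auxin synthesis and transport genes 11 were higher, 7 with the covariate (median 1.39, adjusted p = 0.00259), YUC8 by 3.63 ± 0.42. Of 12 anthocyanin and flavonoid genes 8 were higher, 4 with the covariate (median 1.69, 1.02 after the correction, adjusted p = 0.0035), LDOX by 3.87 ± 0.40. Of 21 cytokinin genes 11 were higher and 1 lower (median 1.68, 0.79 with the covariate, adjusted p = 0.00259, but p = 0.151 with an estimated correlation). CKX4 was higher by 5.25 ± 0.30, and CKX1 differed by -3.14 ± 0.56, without passing with the covariate (-1.27).

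Of 9 auxin response genes 7 were higher in gcn5 than in ada2b-c and 2 lower (median 2.51, 1.40 after the correction and 1.40 with the covariate, adjusted p = 0.0211, but p = 0.181 with an estimated correlation and 0.0564 after the correction). IAA6 and IAA29 were higher by 3.53 ± 0.60 and 3.49 ± 0.31, and the conjugation genes GH3.3 and GH3.5 differed by -3.00 ± 0.43 and -2.80 ± 0.28. Of 19 jasmonate genes 10 were higher and 3 lower (median 1.38, 0.88 with the covariate, adjusted p = 0.0223, but p = 0.181 with an estimated correlation), PDF1.2A by 4.07 ± 0.36, while VSP2 differed by -2.34 ± 0.29. Of 15 cold and abscisic acid genes 9 were higher and 2 lower, 5 and 2 with the covariate (median 1.37, 0.82 after the correction, adjusted p = 0.0431, but p = 0.181 with an estimated correlation and 0.0552 without gcn5 replicate 2), the cold-induced KIN2 (AT5G15970) by 3.84 ± 0.39, while RD20 (AT2G33380) and HAI1 differed by -1.75 ± 0.21 and -1.46 ± 0.28. Of 19 GCN5 complex subunits 10 were lower and 1 higher (10 and 0 over the list alone, median -0.77, adjusted p = 0.00618, but p = 0.154 with an estimated correlation). TRA1A, TRA1B and ADA2A differed by -3.86 ± 0.44, -3.69 ± 0.50 and -2.73 ± 0.48. After the correction TRA1A and TRA1B stood at 0.18 and 0.38, without passing.

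In all, 13567 genes differed between gcn5 and ada2b-c, 6939 higher and 6628 lower (5351 and 7718 with equal totals). GRP19 (AT5G07550) and AT1G66850 were listed at 0 in ada2b-c, and stood at 939 ± 305 and 468 ± 81.4 in gcn5. AT3G01345 differed by -9.46 ± 0.55 and MLP34 (AT1G70850) by -6.61 ± 0.67, and AT3G59580 was listed at 0 in gcn5, against 108 ± 23.1 in ada2b-c. Differences followed transcript length with a rank correlation of -0.61 across genes. The balance was 6027 higher and 6804 lower after the correction, and the count was 7277 with the covariate.

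Also compared were gcn5 and ada2b-cada2a. Photosynthesis genes were higher in gcn5 in 20 of 24 cases (median 0.97, adjusted p = 5.72e-10, but p = 0.157 with an estimated correlation), LHCB2.1 by 3.55 ± 0.15. Of 19 jasmonate genes 11 were higher and 2 lower (median 1.04, adjusted p = 0.00145, but p = 0.157 with an estimated correlation), PDF1.2A by 4.09 ± 0.36. Of 15 cold and abscisic acid genes 8 were higher, 5 with the covariate (median 1.05, adjusted p = 0.015, but p = 0.209 with an estimated correlation), CBF2 by 4.38 ± 0.59. Among 21 cytokinin genes 7 were higher and 1 lower (median 0.79, 0.31 with the covariate, adjusted p = 0.015, but p = 0.298 with an estimated correlation). CKX4 was higher by 2.64 ± 0.30, and CKX1 differed by -2.86 ± 0.56, without passing in a fit of these groups alone (adjusted p = 0.0589) or with the covariate (-1.35).

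Of 13 floral organ identity genes 9 were higher in gcn5 than in ada2b-cada2a, 4 after the correction and 2 with the covariate (median 1.27, 0.75 after the correction, adjusted p = 0.0146, but p = 0.157 with an estimated correlation and 0.0984 after the correction). AP3 was higher by 2.22 ± 0.50, without passing in a fit of these groups alone (adjusted p = 0.0665) or with the covariate (1.97). Of 14 tapetum markers 7 were higher and 2 lower (median 1.61, adjusted p = 0.0312, but p = 0.298 with an estimated correlation and 0.124 without gcn5 replicate 1), EXL6 by 5.03 ± 0.45. In all, 10930 genes differed, 5672 higher and 5258 lower (4258 and 5636 with equal totals). XTH3 (AT3G25050) and LCR66 (AT1G61070) were higher by 6.51 ± 0.51 and 6.16 ± 0.56, and AT1G02813, listed at 0 in ada2b-cada2a, stood at 82.7 ± 21.2. AT1G64795 differed by -6.50 ± 0.43 and BGLU22 (AT1G66280) by -4.65 ± 0.74, the latter without passing with the covariate (-3.17), and AT4G18900, listed at 0 in gcn5, stood at 25.8 ± 5.34. The count was 6890 without gcn5 replicate 3, 7206 in a fit of these groups alone and 7083 with changes of at least 1. It was 8035 after the correction (197 opposite), 3534 with the covariate and 1413 in all 3 fits. The rank correlation with length was -0.66.

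An interaction asks whether a double mutant differs from the sum of the separate changes. For ada2b-c and ada2a, 6 of 12 anthocyanin and flavonoid genes lay above the sum, 7 over the list alone (median 1.79, adjusted p = 0.000474). LDOX lay above it by 3.79 ± 0.56 and DFR (AT5G42800) by 3.41 ± 0.55. Photosynthesis genes lay above the sum in 6 of 24 cases, 7 over the list alone, 11 after the correction and 10 with equal totals (median 0.45, 0.71 after the correction and 0.71 with equal totals, adjusted p = 0.00179, but p = 0.387 with an estimated correlation), LHCB3 by 1.42 ± 0.25. Of 14 auxin synthesis and transport genes 5 lay above it (median 0.91, adjusted p = 0.0148, but p = 0.136 with an estimated correlation and 0.0776 after the correction), YUC3 by 5.11 ± 0.82. Of 9 auxin response genes 2 lay above it and 1 below, 5 and 1 over the list alone (median 1.02, 1.70 after the correction, adjusted p = 0.0235, but p = 0.306 with an estimated correlation), IAA1 by 2.83 ± 0.33. Of 14 tapetum markers 3 lay above it, 5 over the list alone (median 1.74, adjusted p = 0.0235, but p = 0.306 with an estimated correlation). Of 19 jasmonate genes 6 lay below the sum and 1 above, 9 and 2 over the list alone and 2 and 3 with equal totals (median -0.77, -0.29 after the correction and -0.50 with equal totals, adjusted p = 0.0458, but p = 0.306 with an estimated correlation, 0.119 with equal totals and 0.0799 after the correction), JAZ8 by -3.24 ± 0.79, against AOC1 at 1.09 ± 0.27.

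Without ada2a replicate 1 the tapetum, photosynthesis, jasmonate and auxin synthesis lists of this interaction lost their calls (adjusted p = 0.0593 each), as did the auxin response list (0.123). The tapetum (0.0556) and jasmonate lists (0.0902) lost theirs without ada2a replicate 2, and the jasmonate list also without Col-0 replicate 3 (0.052) or ada2b-cada2a replicate 1 (0.07). In all, 3096 genes passed, 1842 above the sum and 1254 below (1907 and 765 with equal totals). The count was 1695 and 2029 without Col-0 replicate 1 and 2, 1837, 1843 and 1844 without ada2b-c replicate 1, 2 and 3, 5223 and 1462 without ada2a replicate 1 and 3, and 1712 without ada2b-cada2a replicate 2. It was 4655 after the correction, 4828 with the covariate and 5173 both in a fit of these groups alone and without the 4 low-slope libraries.

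For ada2b-c and spc, jasmonate genes lay below the sum in 12 of 19 cases, 14 over the list alone (median -1.37, adjusted p = 1.57e-09). JAZ8 lay below it at -4.17 ± 0.79, JAZ10 at -3.15 ± 0.30 and the lipoxygenase gene LOX4 (AT1G72520) at -1.95 ± 0.37. JAZ10 stood at 3119 ± 945 in spc and at 160 ± 20.4 in ada2b-cspc. Photosynthesis genes lay above the sum in 10 of 24 cases, 17 over the list alone and 16 with equal totals (median 0.84, adjusted p = 5.53e-08, but p = 0.219 with an estimated correlation), LHCB3 by 1.53 ± 0.25. Among 14 auxin synthesis and transport genes 5 lay above it, 6 over the list alone (median 0.97, 0.60 after the correction, adjusted p = 0.00109), YUC3 by 3.95 ± 0.82 and PIN7 (AT1G23080) by 2.16 ± 0.27. Among 12 anthocyanin and flavonoid genes 5 lay above it, 3 with the covariate (median 1.26, adjusted p = 0.00385), DFR by 2.95 ± 0.55. Of 9 auxin response genes 2 lay above it, 3 over the list alone (median 1.11, 1.99 after the correction and 1.88 with the covariate, adjusted p = 0.00714, but p = 0.223 with an estimated correlation and 0.0795 without spc replicate 1), IAA29 by 3.37 ± 0.43. Of 12 strigolactone and branching genes 3 lay above it, with 3 above and 1 below over the list alone (median 0.88, 0.56 with the covariate, adjusted p = 0.0336, but p = 0.51 with an estimated correlation, 0.0926 without spc replicate 2 and 0.054 with equal totals), SMXL8 (AT2G40130) by 2.75 ± 0.48.

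For ada2b-c and spc 2481 genes passed, 1366 above the sum and 1115 below (1168 and 777 with equal totals). The count was 1196 and 1469 without Col-0 replicate 1 and 2, 1446, 1331 and 1306 without ada2b-c replicate 1, 2 and 3, 7041, 1256 and 1648 without spc replicate 1, 2 and 3, and 1335, 1439 and 1343 without ada2b-cspc replicate 1, 2 and 3. It was 3888 with replicate number as a block, 5099 without the 4 low-slope libraries, 3090 after the correction (1926 shared) and 1780 with the covariate. In all 3 fits 1185 passed. The rank correlation with length was 0.5.

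The last question was which genes changed in the same direction in more than 1 mutant. For ada2a and spc 7465 genes did, 3744 higher and 3721 lower (2224 and 5611 with equal totals), and 2 changed in opposite directions. From the sizes of the separate sets 998 and 1188 would be shared if they were independent. PR1, JAZ8 and THI2.1 were among those higher in both. Their log2 changes correlated at 0.84 across genes, where 100 simulations of unchanged groups with the same controls gave a median of 0.53 and at most 0.80. After the correction it was 0.78, with at most 0.81 in simulations. The simulated groups shared a median of 0 calls in every pair, and at most 923, for ada2b-c and ada2a. For gcn5 and ada2b-c 5986 genes changed in the same direction, 2545 higher and 3441 lower, against 1174 and 1468, and 381 went opposite ways. The correlation was 0.67 (simulated median 0.52, highest 0.90), and 0.68 after the correction (highest 0.77). The balance was 3593 and 2296 with equal totals, 3761 and 3731 without gcn5 replicate 3, 3841 and 3807 without the 4 low-slope libraries, and 3479 and 3471 after the correction. PR1, PR2, ALD1, FMO1 and UGT76B1 were higher in both, and LHCB2.1, LHCB3 and CBF1 to CBF3 lower in both. For ada2b-c and ada2a 1370 genes shared a direction and 4832 went opposite ways, and for ada2b-c and spc 1557 and 6086, with correlations of -0.27 and -0.31 (simulated medians 0.55 and 0.54). After the correction 2015 and 2146 shared a direction (1041 and 1118 of them higher), 3222 and 3882 went opposite ways, and the correlations were -0.12 and -0.11. Because the same 3 Col-0 libraries enter each pair and cannot be split into separate controls of 2, part of any excess may come from them. The count for ada2a and spc was 4181 without Col-0 replicate 1, 4049 without ada2a replicate 3, 2760 in fits of the groups compared alone, 4098 with changes of at least 1 and 1785 with the covariate. That for ada2b-c and ada2a was 878 without Col-0 replicate 1, 810 without ada2a replicate 3 and 550 with changes of at least 1, and that for ada2b-c and spc was 693 with changes of at least 1 and 949 with the covariate.

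Among the lists that passed in none of the 6 mutants against Col-0 were flowering-time regulators, pollen, seed and embryo, and root markers, and genes of the meristem, the mitotic cell cycle, leaf senescence, gibberellin, brassinosteroid and strigolactone pathways, heat shock and the circadian clock. Senescence genes passed after the correction in ada2b-cspc (adjusted p = 0.0337, but p = 0.0895 with an estimated correlation). The lowest adjusted p among these lists was 0.0656, for brassinosteroid biosynthesis genes in ada2b-c, of which 5 of 10 fell, with a median of -0.94. That list passed without ada2b-c replicate 3 (adjusted p = 0.0493) and after the correction (adjusted p = 0.0333, but p = 0.0846 with an estimated correlation).

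Some other list calls also depended on the setting. Auxin response genes passed with equal totals in ada2b-cada2a (adjusted p = 0.035, but p = 0.151 with an estimated correlation) and ada2b-cspc (adjusted p = 0.046, but p = 0.188 with an estimated correlation). After the correction jasmonate genes passed for ada2b-cspc against ada2b-c (adjusted p = 0.0119, but p = 0.11 with an estimated correlation), brassinosteroid genes for gcn5 against ada2b-c (adjusted p = 0.0321, but p = 0.101 with an estimated correlation), and auxin response genes for gcn5 against ada2b-cada2a (median -0.40 in place of 0.23, adjusted p = 0.0178, but p = 0.184 with an estimated correlation). Salicylic acid genes passed after it in the interaction with spc (median -0.65, adjusted p = 0.000685, and p = 0.0413 with an estimated correlation).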

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

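Of the tests in this part, the counts by side and the shuffles of residuals were chosen after the result was seen. Groups of 3 libraries were not tested for outliers. The interactions were flagged because the effect of the second mutation differed between plants with and without the ada2b-c mutation, in 3096 genes for ada2a and 2481 for spc. In fits of these groups alone 4 of 100 splits of the libraries reached the real count for ada2a (5173, 9300 at most in another). For spc 3 of 100 did (3605 and 11932), and both shares include the real split. Some splits gave more, so chance is not excluded. The split with 11932 points to a structure of the samples: all 3 and 2 others as large put at least 5 of the 6 libraries with the ada2b-c mutation on 1 side of the contrast, so they mix in that mutation's own effect. The 92 with fewer gave at most 1 call each. With residuals shuffled and both separate effects kept, 2 and 3 of 100 gave as many (7939 and 10840 at most in another).

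The genes with the largest interactions stood out for the same reason. A group listed at 0 enters these values as 0 on the log2(value + 1) scale, so they are no bound on a ratio. For ada2a they were ACOS5 (AT1G62940), for an enzyme of pollen wall synthesis, at 6.27, AT3G28330 at 6.13, AT1G10300 at 5.97, AT3G01345 at -8.46, AT3G59930 at -6.90 and ADA2A at -6.57. For spc they were AT2G01422 at 10.14, SDG21 (AT2G24740) at 5.76, FUT6 (AT1G14080) at 5.74, AT3G01345 at -9.98, ddf2 (AT1G63030), for a relative of the CBF proteins, at -7.59 and LTP4 at -6.64.

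For each of the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The real split, alone among the 10 (1 split), gave 5429 calls in gcn5, 16626 in ada2b-c, 4804 in ada2a, 4443 in spc, 15521 in ada2b-cada2a, 16192 in ada2b-cspc and 12855 for gcn5 against ada2b-c, with 0 as the highest other count. It gave 8861 for ada2b-cada2a against ada2b-c, 7363 for ada2b-cspc against ada2b-c and 7206 for gcn5 against ada2b-cada2a, with 9, 5 and 3 as the highest other counts. For spc against ada2a all 10 splits gave 0.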

How the results depend on the processing

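The alternative settings were chosen before any result was seen, except 7 added after. Relative log expression scaling and DESeq2, both planned, need counts and were not run. The cause of the shifts below was not tested. Without a filter on low values and with a pseudocount of 0.1 every count stayed within 1.5 times its first value. With replicate number as a block the interaction of ada2b-c and spc counted 3888. Same-numbered residuals correlated above 0.1 in 20 of 63 pairs, over a range of -0.30 to 0.68, and 13 of 21 libraries matched their own number best. Only in Col-0, gcn5 and ada2a did every pair pass 0.1. A block within these 3 gave 9744 genes for gcn5 and 11212 for ada2a, and 10726 and 9093 with the correction. It ended no call of a list or named gene, and apart from GCN5 and ADA2A gave no new one.

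With changes of at least 1 the counts were 5382 for ada2a, 6947 for spc, 2169 for ada2b-cada2a against ada2b-c, 1423 for ada2b-cspc against ada2b-c, 7083 for gcn5 against ada2b-cada2a, and 4098, 550 and 693 for calls shared by ada2a and spc, ada2b-c and ada2a, and ada2b-c and spc. This filter can only lower a count. In fits of only the groups compared they were 4804 for ada2a, 4443 for spc, 8861 and 7363 for the double mutants against ada2b-c, 0 for spc against ada2a, 7206 for gcn5 against ada2b-cada2a, 5173 for the interaction with ada2a and 2760 for calls shared by ada2a and spc.

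With the correction the counts were 5494 and 3600 for the double mutants against ada2b-c and 642 for spc against ada2a. The interaction with ada2a gave 4655. With the covariate they were 10003 for ada2b-c, 3745 for ada2a, 3146 for spc, 9632 for ada2b-cada2a, 9959 for ada2b-cspc, 6965 and 4998 for the double mutants against ada2b-c, 1611 for spc against ada2a, 7277 for gcn5 against ada2b-c, 3534 for gcn5 against ada2b-cada2a, 4828 for the interaction with ada2a, and 1785 and 949 for calls shared by ada2a and spc and by ada2b-c and spc. Without the 4 low-slope libraries they were 6583 and 4166 for the double mutants against ada2b-c and 598 for spc against ada2a. The interactions gave 5173 and 5099.

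With an estimated correlation 2 lists passed in gcn5, 6 in ada2b-c, 0 in spc, 2 in ada2b-cada2a and 2 in ada2b-cspc, and with the length and GC correction 5 in ada2b-cada2a, against 6, 10, 5, 8 and 10 at first. Leaving out 1 library gave 6 to 6 lists in gcn5, 10 to 11 in ada2b-c, 0 to 2 in ada2a, 2 to 5 in spc, 7 to 8 in ada2b-cada2a and 9 to 10 in ada2b-cspc.

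Leaving out 1 library gave counts of 4600 to 10305 for ada2a, 6730 to 12684 for spc, 2265 to 2534 and 1234 to 1639 for the double mutants against ada2b-c, 82 to 564 for spc against ada2a, 6890 to 11942 for gcn5 against ada2b-cada2a, and 1462 to 5223 and 1196 to 7041 for the interactions. Shared calls numbered 4049 to 8547 for ada2a and spc and 810 to 1637 for ada2b-c and ada2a. The others stayed within 1.5 times.

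Of 311 named results that passed, the settings chosen beforehand gave 3278 values, of which 3218 kept the call, 60 lost it and 0 turned. With the correction 295 kept it, 6 lost it and 10 turned. Those that turned were GCN5 in ada2b-cada2a (-0.12) and ada2b-cspc (-0.05), TRA1B in ada2b-c (-0.18) and ada2b-cspc (-0.17), TRA1A and TRA1B for gcn5 against ada2b-c (0.18 and 0.38), TAF10 and ENY2 in ada2b-c (0.76 and 0.55), and PDF1.2A and LOX2 in spc (-0.05 and 0.06). TAF10 and ENY2 in ada2b-c also turned with the covariate (0.56 and 1.29), and TAF10 with equal column totals (0.02).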

Other observations

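A few genes set single genotypes apart. AT3G01345 stood at 1757 ± 107 in ada2b-c, and in both double mutants, which carry the same mutation, it differed from that by -7.77 and -8.69 log2 units. AT2G01422 stood at 5625 ± 735 in ada2b-cspc and 8.78 ± 3.23 in ada2b-c.

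The artifact tests of the first pattern below were chosen after the result was seen. The log2 changes of ada2b-c follow transcript length. Their correlation, in size, with the leading axis of residuals within the other 5 genotypes was 0.52, so a difference between libraries that is not genotype, such as RNA integrity or fragment size, fits. That axis held 51.3% of the residual variance. A rank correlation of 0.2 with GC content after removing length, and a share of 0.94 of the variance of the slopes lying between genotypes, cannot tell these sources apart. Hypothesis: part of the changes may come from RNA integrity, which could be tested by measuring it in the same RNA.

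The fall of photosynthesis genes in ada2b-c had a list median of -2.41 after the correction, -2.37 with equal totals and -2.93 with the covariate. A length trend, the scaling and the library axis, as modelled, therefore cannot be its only source. Of 10000 random lists matched to it the lowest median was -1.88.

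The log2 changes of ada2a and spc had a covariance of 0.96 across genes, and 0.64 after the correction. In 100 simulations with only shared controls the highest were 0.28 and 0.21, which argues against these alone. The corrected correlation was 0.78, against at most 0.81 simulated. RNA integrity was not tested. Hypothesis: both gene products may share targets, which 0.64 leaves open and their binding sites could test.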
